A study of Bifidobacterium bifidum with 4 samples.

How the data were processed

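The series measured total RNA of B. bifidum PRL2010 in lag, early exponential, late exponential and early stationary phase, with 1 sample per phase. Per the labels' protocols, cells grew anaerobically in MRS medium with 0.05% cysteine at 37 °C, as stated for 3 of the 4 samples, RNA was extracted after lysis with glass beads and treated with DNase, and 5 µg from 1 pool of total RNA was amplified and labelled with Cy5. Nothing in the labels names separate cultures, so the 2 array files of a sample were taken as repeat arrays, and their spread as technical. Samples were grouped by the phase in their titles.

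Each array file lists, per the file headers, the mean, median and standard deviation of the foreground intensity over the repeat spots of every probe, with the numbers of spots included, excluded and present. The deposited intensities carry no background column and were not normalized between arrays. The deposited spot counts per probe gave 41514 spots per array, of which 0 to 527 had been excluded. The median coefficient of variation between spots of a probe was 13.4% to 39.6% per array, highest in early stationary phase. The scanner, its software and the annotation behind the probes are not given in the sources used here. The authors also deposited a value table of intensities with 1 column per phase, whose making is not stated. Quantile normalization of the 8 arrays' spot medians followed by averaging each pair gave 99.9% of its values within 1%, at a median ratio of 1.00. Its scale is therefore linear intensity and its columns have medians of 485, 483, 478 and 478 from lag to early stationary phase.

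The 1902 probes comprise 1822 gene probes, 1 for each BBIF number, 47 negative controls, 19 factory quality probes and 14 probes named after other database records. Of the gene probes 1785 have 35 bases, and the longest has 40. Names, sequences and groups of probes come from the array files. The reference table of the species is of another strain, and 0 of the 1822 numbers matched it, so no gene is named. The rule fixed for named genes asked for genes with a named product and so gave none. In its place, the 2 largest changes each way among probes that passed the rule below were taken for each comparison, and the 2 probes of smallest range among those detected in every phase. The functional gene lists and the list of common reference genes prepared for this work could not be applied for the same reason.

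The main values were log2(mean intensity + 50), quantile normalized over the 1822 gene probes of the 8 arrays, and averaged over the 2 arrays of a sample. A probe was detected in a phase when its intensity exceeded the 95th percentile of the negative controls on both arrays. A probe counted as higher or lower when it was detected in either phase, its means differed by at least 1 log2 (2-fold) and the values of the 2 arrays of one phase did not overlap those of the other. Counts were set beside the same counts after 1 array was swapped between the phases, and beside the 33.3% of probes that would not overlap by chance. A probe whose arrays do not overlap between the phases cannot pass after a swap, so low swapped counts follow in part from that separation. The 33.3% leaves out the floor, which admits probes through 1 phase and can favour separation. The phases have no replicate samples, so no test was made and no p-value is given. Where a probe was not above the floor on either array of a phase, the fold is given as a lower bound: the mean of the brighter phase against, on each array of the dimmer phase, the higher of the lowest normalized value among detected probes and the probe's own. Such a bound holds for the main normalization with all arrays. Fold changes are on the log2(intensity + 50) scale and without background subtraction, both of which understate changes of dim probes. Probes at the saturation value of 65535 numbered 1 on the second lag array and 5 and 2 on the early stationary arrays, and were kept.

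The alternatives were median centring and 75th percentile centring in place of quantile normalization, no added offset, no floor, the authors' value table, the fold rule alone, and leaving out arrays. Those chosen after seeing the data were spot medians, a normexp background from the negative controls (limma 3.58.1, function nec, robust), a floor at the median of the negative controls, a floor without the 2 brightest of them, and only the 1768 probes whose names end in S. Scaling shifts the median of all gene probes: with 75th percentile centring it lay at 0.20 log2 for early exponential against lag, -0.13 for late against early exponential and -0.24 for early stationary against early exponential phase, while quantile normalization kept it within 0.05. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

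The counting rule was tested on simulated data in which 200 of the 1822 gene probes were changed by known amounts in each of 10 draws. Among probes that could be counted, rises of 1.5 log2 were recovered for 75.3% (early exponential against lag), 86.9% (late against early exponential), 85.7% (early stationary against late exponential) and 82.8% (early stationary against early exponential). Rises of 2.5 log2 were recovered for at least 99.4% in each comparison. Falls of 1.5 log2 were recovered for 92.5%, 100%, 100% and 89.7% in the same order, from 27 to 40 probes each. The rates for rises of 1.5 log2 rest on 170 to 291 probes. Changed probes detected in neither phase are left out of these rates, which therefore overstate the share of all simulated changes recovered. Unchanged probes were counted in 14.4%, 7.17%, 4.39% and 7.67% of cases, with median estimates of -0.34, -0.29, -0.39 and -0.30 log2. The median estimates of the same probes were 0.00 without normalization and -0.02 to 0.01 with median centring, so in these simulations the downward shift came with quantile normalization. More rises than falls could be counted in the simulations, 289 against 28 of 1.5 log2 for late against early exponential phase. The data gave 10 rises and 39 falls there. The simulated 14.4% also exceeds the 3.85% of all considered probes counted in the data for early exponential against lag. The simulated rates and shift therefore do not carry over to the data. The number of arrays, 2 per sample, limits the precision of every value.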

Results

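RNA levels of Bifidobacterium bifidum PRL2010, an anaerobic gut bacterium first obtained from infant stool, were measured on oligonucleotide arrays in 4 growth phases: lag, early exponential, late exponential and early stationary. Each phase was represented by 1 sample of Cy5-labelled RNA and by 2 arrays of that sample. The title of the series names its purpose, the choice of reference genes for quantitative PCR, which calls for genes whose RNA level stays level across growth. Each array held 1822 probes for genes, with 21 to 26 spots per probe, and 47 negative-control probes. No phase had a second sample. None of the differences between phases therefore has a replicate check, no test was made, and every SD below is the SD between 2 arrays of 1 sample. The files identify each probe by a BBIF number and do not pair these numbers with gene names, and none of the 1822 numbers was found in the reference table. The results are therefore given per probe, with at most 2 probes each way in a comparison.

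Most gene probes were not above the floor set by the negative controls. The median gene probe had an intensity of 435 to 588 on the 8 arrays, and the median negative control 356 to 570. Between 41.0% and 61.8% of the gene probes on an array were brighter than its median negative control. A probe was taken as detected in a phase when both arrays exceeded the 95th percentile of the negative controls, which lay between 1013 and 2102. By this rule 186 gene probes (10.2%) were detected in lag phase, 181 (9.93%) in early exponential, 106 (5.82%) in late exponential and 149 (8.18%) in early stationary phase. The floor was highest on the late exponential arrays, at 2102 and 1937, and these arrays also had the fewest detected probes. Over all phases 259 probes (14.2%) were detected at least once, 72 (3.95%) in every phase and 1563 in none. Early stationary phase had 46 probes detected in no other phase, against 17 for lag, 16 for early exponential and 3 for late exponential phase.

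**Figure D1:**
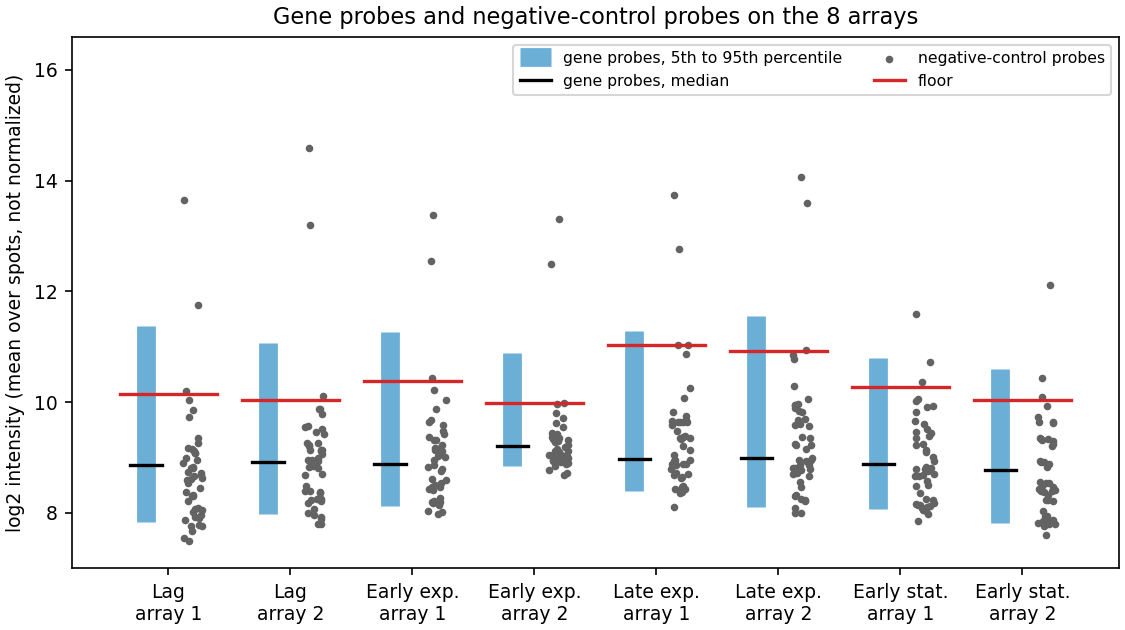
Log2 intensity before normalization on each of the 8 arrays: bars span the 5th to 95th percentile of the 1822 gene probes, black lines mark their median, points are the 47 negative-control probes and red lines mark the floor. The bulk of the gene probes lies in the range of the negative controls, and the brightest negative control reaches 24576 on the second lag array.

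RNA profiles in early stationary phase were the least similar to those of the first 2 phases. Across gene probes, which are not independent replicates, lag and early exponential arrays correlated at a mean Pearson r of 0.927, early and late exponential arrays at 0.883, and late exponential and early stationary arrays at 0.829. The lowest means were 0.743 for early exponential with early stationary and 0.747 for lag with early stationary phase. Most of these probes were detected in no phase. Over the 259 probes detected at least once, the means were 0.890, 0.736 and 0.621 in the same order. They were 0.378 for early exponential and 0.460 for lag with early stationary phase, while arrays of the same sample correlated at 0.837 to 0.979. Detection in 1 phase admitted a probe, which can favour differences between phases. Across all gene probes, arrays of the same sample correlated at 0.983 in late and 0.949 in early exponential phase. They correlated at 0.942 in early stationary and 0.892 in lag phase. The 2 lag arrays were thus less alike than the lag and early exponential arrays were, whose correlations ran from 0.910 to 0.936. The root mean square SD between the arrays of a sample was 0.31 log2 in lag, 0.21 in early exponential, 0.12 in late exponential and 0.23 in early stationary phase.

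**Figure D2:**
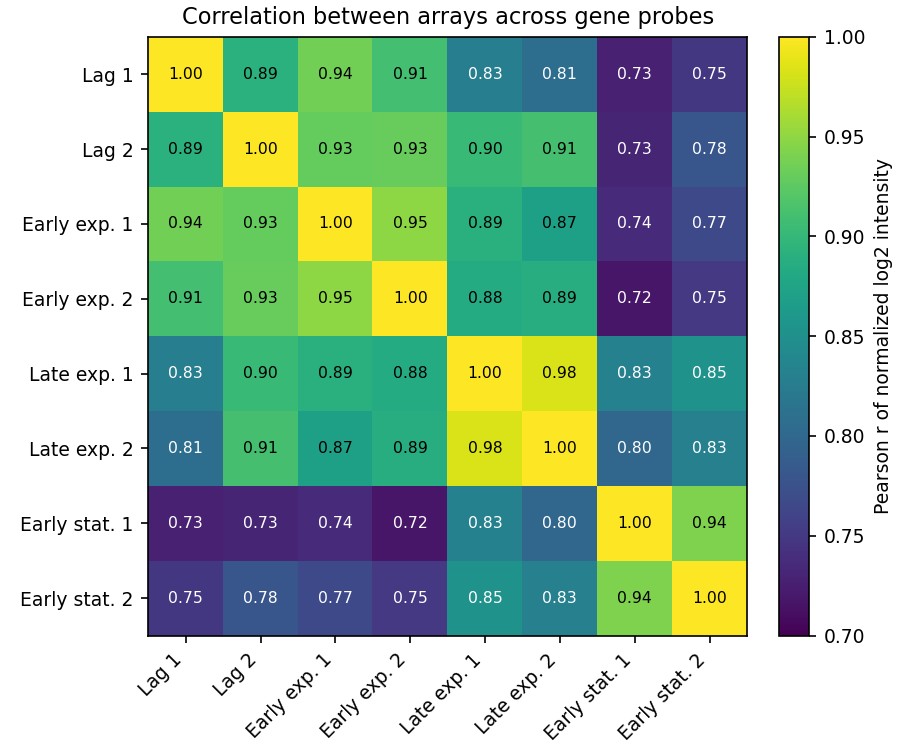
Pearson correlation of normalized log2 intensity over the 1822 gene probes for each pair of the 8 arrays. The late exponential arrays have the highest correlation of any pair (0.983), and pairs of an early exponential and an early stationary array average 0.743.

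With all arrays, few probes differed between early exponential and lag phase, 8 against 5 and 1 when 1 array was swapped between the phases. Of 208 probes detected in either phase, 5 were at least 2-fold higher and 3 at least 2-fold lower in early exponential phase with no overlap of the arrays. Swapping 1 array between the phases gave 5 and 1 such probes in the 2 possible arrangements, and 36.1% of the probes had arrays that did not overlap, against 33.3% by chance. The largest increase was for BBIF01158_4_35_S, which was not above the floor on either lag array and rose at least 2.38-fold, from a mean of 9.64 ± 0.29 to 11.38 ± 0.24 log2 (SD, 2 arrays). BBIF01841_329_35_S differed by 1.14 log2, from 12.64 ± 0.38 to 13.78 ± 0.00, but by 0.37 and 0.52 when arrays were centred on the median or the 75th percentile, and by 0.88 without the second lag array. The SD of 0.00 arises because quantile normalization gives probes of equal rank equal values. The largest decreases were -1.42 log2 at BBIF00556_101_35_S and -1.28 log2 at BBIF00991_222_35_S, the latter at least 2.20-fold to below the floor. Without the first lag array these differences were -0.83 and -0.51 log2, and without the second early exponential array the former was -0.82. Leaving out 1 array, which also loosens the rule, moved the counts. They were 9 higher and 13 lower without the first lag array, and 7 and 23 without the second. Without the first early exponential array they were 15 and 4, and without the second 13 and 1. Median centring left 1 probe higher and 9 lower, and 75th percentile centring 1 higher and 6 lower, so that the share of higher probes among those that passed moved from 62.5% to 10% and 14.3%.

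From early to late exponential phase 39 probes fell at least 2-fold and 10 rose, out of 187 detected in either phase. The strongest falls were at 2 probes with successive numbers. BBIF01841_329_35_S (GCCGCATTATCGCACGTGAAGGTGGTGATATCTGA) fell by 2.99 log2, from 13.78 ± 0.00 to 10.78 ± 0.16, and was below the floor on 1 of the 2 late exponential arrays. BBIF01842_77_35_S (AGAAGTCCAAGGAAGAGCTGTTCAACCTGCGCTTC) fell by 2.72 log2, from 13.60 ± 0.10 to 10.88 ± 0.15, and was above the floor in both phases. The strongest rises were at BBIF00337_1083_35_S (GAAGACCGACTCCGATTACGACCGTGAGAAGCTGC), by 2.67 log2 from 11.72 ± 0.05 to 14.39 ± 0.40, and at BBIF00869_241_35_S (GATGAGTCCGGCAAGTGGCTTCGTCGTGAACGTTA), by 2.44 log2 from 12.70 ± 0.28 to 15.14 ± 0.27. These 4 probes kept their direction and stayed beyond 2-fold under both centrings. The swapped arrangements gave 1 and 0 probes, and the arrays did not overlap for 79.1% of the probes. Here and in the comparisons below, the low swapped counts follow in part from that separation. Of the 187 probes, 100 were detected in both phases, and the others entered through 1 phase, which can favour separation. Of the 39 probes that fell, 34 were not detected in late exponential phase. The floor was higher there, at 2102 and 1937, than on the early exponential arrays, at 1327 and 1013. Of the 39, 15 had numbers between 1818 and 1862, a stretch noticed after the values were seen. The balance of rises and falls rested on the scaling: 20.4% of the probes that passed were higher in late exponential phase with quantile normalization, 55.6% with median centring (40 higher, 32 lower) and 44.4% with 75th percentile centring (28 higher, 35 lower).

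**Figure D3:**
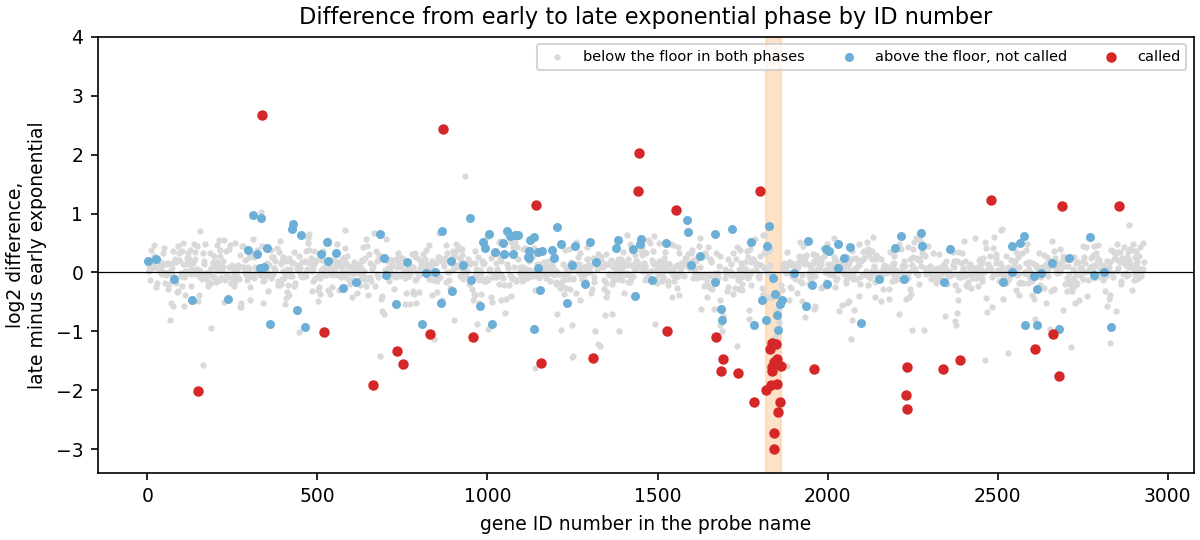
Log2 difference between late and early exponential phase for each gene probe against the number in its name, with the stretch from 1818 to 1862 shaded. The shaded stretch holds 15 of the 39 probes that fell at least 2-fold.

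From late exponential to early stationary phase 32 probes rose and 36 fell at least 2-fold out of 179. BBIF00491_756_35_S (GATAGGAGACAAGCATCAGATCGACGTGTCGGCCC) was not above the floor on either late exponential array and rose at least 4.34-fold, to 12.92 ± 0.87 log2. BBIF02280_632_35_S (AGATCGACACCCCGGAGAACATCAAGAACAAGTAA), also not above the floor in late exponential phase, rose at least 2.92-fold, to 12.35 ± 1.02. BBIF01997_1064_35_S (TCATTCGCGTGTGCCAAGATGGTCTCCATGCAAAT) fell from 15.14 ± 0.27 to 9.83 ± 0.44 log2. Neither early stationary array was above the floor for it, and it was at least 25.9-fold lower. BBIF01526_1255_35_S (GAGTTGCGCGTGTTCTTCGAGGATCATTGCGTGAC) fell from 13.93 ± 0.63 to a level below the floor on both arrays and was at least 11.1-fold lower with the main scaling. Its plain difference was -3.98 log2, and -3.36 with spot medians, an alternative chosen after seeing the data, which is under that bound. The 2 swapped arrangements gave 1 probe each, and the arrays did not overlap for 78.8% of the probes. Of the 32 probes that rose, 25 were undetected in late exponential phase, where the floor was highest. Of the 36 that fell, 23 were undetected in early stationary phase. The share of higher probes was 47.1% with quantile normalization and 27.3% under each of the other 2 scalings, which both gave 21 higher and 56 lower. The balance turned the other way with the normexp background, chosen after seeing the data (51 higher, 44 lower). It also turned without the second early stationary array (47 and 43) and without the second array of every phase (46 and 39).

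Between early exponential and early stationary phase, the pair of phases with the lowest correlation, 47 probes were higher and 68 lower at least 2-fold in early stationary phase out of 239. BBIF01800_245_35_S (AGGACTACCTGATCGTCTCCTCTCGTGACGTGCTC) was not above the floor in early exponential phase and was at least 8.24-fold higher in early stationary phase, at 13.31 ± 0.06 log2. BBIF00491_756_35_S was at least 6.30-fold higher with the main scaling and all arrays, with a plain difference of 2.98 log2. That difference was 2.57 log2 with 75th percentile centring, 2.36 without the second early stationary array and 2.28 without the second array of every phase, all under the bound. BBIF01997_1064_35_S was at least 29.5-fold lower, from 15.33 ± 0.33 log2 in early exponential phase. BBIF01841_329_35_S was at least 10.05-fold lower, from 13.78 ± 0.00. Its means were 10.78 ± 0.16 in late exponential and 9.20 ± 0.23 in early stationary phase. The swapped arrangements gave 1 probe each, and the arrays did not overlap for 84.9% of the probes. Of the 239 probes, 91 were detected in both phases, and 24 of the 115 that passed were among them. Of the 47 higher probes, 32 were undetected in early exponential phase. Of the 68 lower probes, 59 were undetected in early stationary phase. With 75th percentile centring 30 probes were higher and 73 lower, a share of 29.1% higher against 40.9% with quantile normalization, and 37.6% with median centring.

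**Figure D4:**
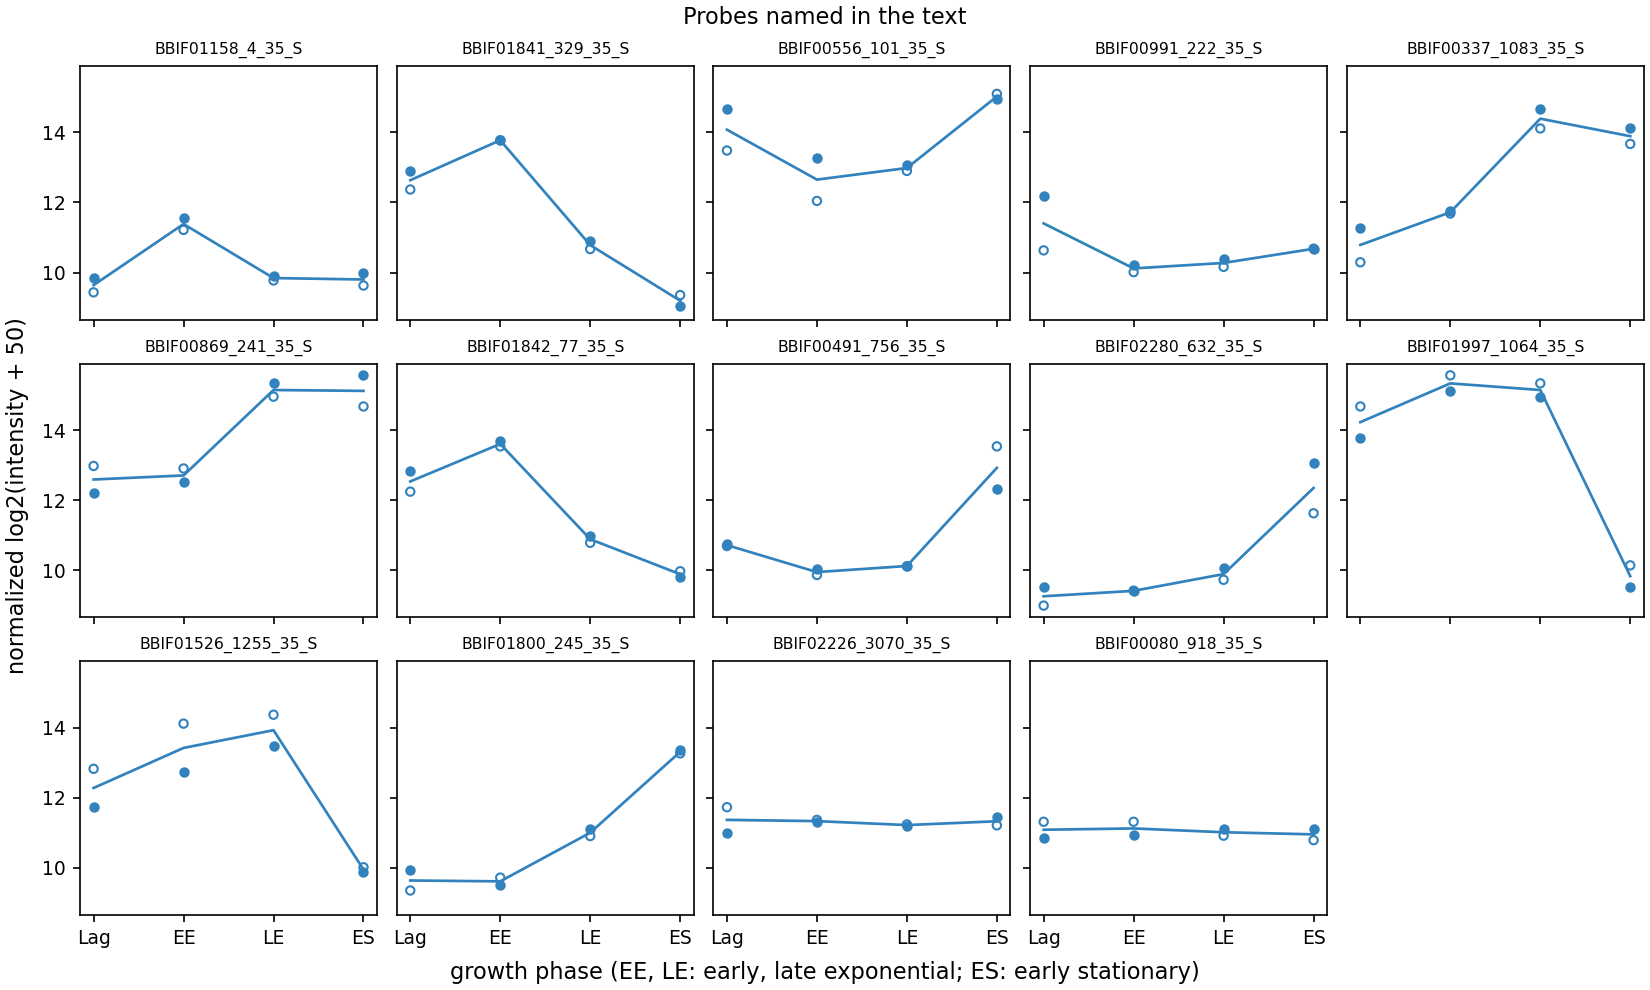
Normalized log2(intensity + 50) of the probes named in the text over lag, early exponential (EE), late exponential (LE) and early stationary (ES) phase. Filled and open points are the first and second array of each sample and lines join their means. BBIF01997_1064_35_S drops from 15.14 in late exponential to 9.83 in early stationary phase, and the last 2 panels show probes with a range under 0.5.

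Over the 4 phases together, 165 of the 259 detected probes had phase means at least 1 log2 apart. The highest mean was in early stationary phase for 56 of them, in early exponential for 46, in late exponential for 39 and in lag phase for 24. The lowest mean was in early stationary phase for 85, in lag for 31, in late exponential for 25 and in early exponential phase for 24. A probe detected in only 1 phase can tend to peak there. Of the 259, 46 were detected only in early stationary, 17 only in lag and 16 only in early exponential phase. Late exponential phase, where the floor was highest, had 3. These counts of highest and lowest means did not use the overlap rule and were made with the main scaling alone.

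Genes with a level profile were sought for the question of the series' title. A range of the 4 phase means under 0.5 log2 and a mean above the median of all gene probes was met by 340 probes. Of these, 315 (92.6%) were detected in no phase, 14 in some and 11 in all. Among probes above the median, 37.3% of the gene probes and 39.1% of the negative controls (9 of 23) met the rule. For 102 of the 340 the SD over phases was smaller than the standard error that the 2 arrays gave a phase mean. The 11 detected probes came from the 72 detected in every phase, whose median range was 1.00 log2. Without the first lag array 6 detected probes met the rule, without the first early exponential array 7, and without the first late exponential array 16. Under 2 alternatives chosen after seeing the data, the number was 185 with the floor at the median of the negative controls and 5 with the normexp background. The smallest range was at BBIF02226_3070_35_S (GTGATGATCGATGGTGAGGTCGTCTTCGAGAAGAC), 0.15 log2, with means of 11.36 ± 0.51, 11.33 ± 0.05, 11.22 ± 0.03 and 11.33 ± 0.17 (SD, 2 arrays) from lag to early stationary phase. The next was at BBIF00080_918_35_S (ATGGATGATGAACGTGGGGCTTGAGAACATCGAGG), 0.17 log2, with means of 11.08 ± 0.32, 11.12 ± 0.27, 11.01 ± 0.14 and 10.95 ± 0.23. Both ranges were smaller than the SD between the lag arrays. Leaving out arrays ended the call for both probes: the range of BBIF02226_3070_35_S was 0.51 without the first lag array and 0.52 without the first array of every phase, and that of BBIF00080_918_35_S was 0.53 without the first array of every phase. With median centring they were 0.62 and 0.58 log2, and with 75th percentile centring also 0.62 and 0.58. Under each of these centrings, 0 probes detected in every phase met the rule.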

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

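Both probes given here are negative controls that lay outside the comparisons and were, on average over the arrays, brighter than nearly all gene probes. The brightest reached a mean intensity of 24576 on the second lag array and was never under 3098 on any array. Its means were 18732 in lag, 10349 in early exponential, 15483 in late exponential and 3773 in early stationary phase. Averaged over the arrays, 11 gene probes were as bright.

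The second brightest negative control reached 12403 on a late exponential array, with a lowest value of 515, and 23 gene probes were as bright on average. Its means were 6423, 5904, 9705 and 580 from lag to early stationary phase. Leaving both out, an alternative chosen after seeing the data, lowered the floor on the late exponential arrays from 2102 to 1746.5 and from 1937 to 1656, and the number of gene probes detected in that phase rose from 106 to 133. In lag, early exponential and early stationary phase it rose from 186 to 237, 181 to 244 and 149 to 195. No explanation for their signal was tested.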

How the results depend on the processing

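The alternatives in this part were fixed before the data were examined, except 5: the spot medians, the normexp background, the floors at the median of the negative controls and without the 2 brightest of them, and the restriction to probes ending in S were chosen after seeing the data. No named probe's difference changed sign under the alternatives run, but which of higher and lower probes were more numerous did change. For early exponential against lag it turned with both centrings and without the first lag array (9 higher and 13 lower), the second (7 and 23) or the second array of every phase (8 and 22). It also turned for late against early exponential with median centring, and for early stationary against late exponential with the normexp background (51 and 44) and without the second early stationary array (47 and 43) or the second array of every phase (46 and 39). Leaving aside 32 recomputed counts that do not use the array left out, 135 counts stayed within 1.5 times the main count and 37 did not. No paired analysis was possible because each phase has 1 sample. Mean over probes of a gene was not run, since each number has 1 probe, and the gene lists and reference genes were not run for lack of gene names.

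Main counts of higher and lower probes were 5 and 3 for early exponential against lag, 10 and 39 for late against early exponential, 32 and 36 for early stationary against late exponential, and 47 and 68 for early stationary against early exponential phase. With median centring they were 1 and 9 in the first comparison, 40 higher in the second, and 21 and 56 in the third, and the 11 level probes detected in every phase became 0. With 75th percentile centring they were 1 and 6, 28 higher, 21 and 56, and 30 higher in the fourth, and again 0 level probes. Without a floor 69 were lower in the third comparison, as with the floor at the median of the negative controls, which gave 185 level probes. Spot medians gave 3 higher in the first comparison. The normexp background gave 15 and 10 in the first, 27 higher in the second, 51 higher in the third and 73 higher in the fourth, with 5 level probes. With it every named difference was larger in size. That of BBIF01997_1064_35_S between early stationary and early exponential phase was -6.98 log2, against -5.51 with the main scaling. Leaving out arrays gave 5 to 15 higher and 1 to 23 lower in the first comparison, 36 to 56 lower in the third and 6 to 16 level probes; the 23 came without the second lag array, the 15 without the first early exponential array, and the 6 without the first lag array. The cause was not tested.

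With median centring, 1 of 5 rises and 2 of 3 falls of the first comparison were also counted, 10 of 10 and 32 of 39 of the second, 18 of 32 and 36 of 36 of the third, and 34 of 47 and 61 of 68 of the fourth. The 10 shared rises of the second comparison were among 40 counted with median centring. Ranking by the SD or the coefficient of variation over phases chose 10 of the same 11 level probes each. Both measures use the same phase means of the same probes as the range, so this overlap was largely built in and is no independent check. Signal over background limits all of these results, because 1563 of the 1822 gene probes were detected in no phase.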

Other observations

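The tests of successive numbers far apart in the list, of pairs sharing 8 or more bases, of pairs outside the window, of the brightest probes, of joint transcription and of the place of the second lag array were chosen after the results they bear on were seen, as was the window of numbers.

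The falls from early to late exponential phase were concentrated in 1 stretch of BBIF numbers. Between numbers 1818 and 1862 lay 15 of the 39 probes that fell at least 2-fold, with a median change of -1.67 log2 (-2.99 to -1.19), BBIF01841_329_35_S and BBIF01842_77_35_S among them. In the window of 50 numbers from 1818, 24 probes were detected in either phase and 22 of these had a lower mean in late exponential phase. Of all 39 gene probes in the window 32 were lower, with a median of -0.73 log2. In 10000 shuffles of the calls among detected probes no window of 50 held more than 13, so 0 reached 15. The count was 14 under median and 75th percentile centring, 17 with the normexp background, and 15 or 16 when 1 early or late exponential array was left out. The 15 probes had median levels of 11.66 in lag, 11.88 in early exponential, 10.11 in late exponential and 9.29 log2 in early stationary phase, where 13 of them were undetected. For early stationary against early exponential phase, the same window held 24 probes detected in either of those 2 phases. Of these, 18 were at least 2-fold lower in early stationary phase, and the highest window count of 10000 shuffles was 16. Of the 8 scans, 1 each way in 4 comparisons, these 2 exceeded all their shuffles and the others did not; both rest on the early exponential arrays. The files do not say which genes these are.

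Differences at neighbouring numbers were correlated, and much of this came from the same stretch. Over 992 pairs of successive numbers the differences between late and early exponential phase correlated at r = 0.302 across probes, against a highest value of 0.113 in 10000 shuffles, and the correlation declined to 0.19 for numbers 2 apart, 0.11 for 10 apart and 0.05 for 20 apart. Without the window of 50 numbers it was 0.151 for 962 pairs of successive numbers. The value for successive numbers was 0.20 between early stationary and early exponential, 0.12 between early exponential and lag and 0.04 between early stationary and late exponential phase.

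Closeness in the array list alone does not account for the link between successive numbers, but a part played by list order was not excluded. Successive numbers more than 100 places apart in the list still correlated at 0.291 (539 pairs), a test chosen after the results were seen. List neighbours with distant numbers correlated at 0.103, just over the bound of 0.1 set in advance, so that test did not exclude list order. Neither test was run without the window, where successive numbers correlated at 0.151. Shared sequence does not account for the link between successive numbers. The longest stretch shared by a pair was 11 bases, and without the 21 pairs sharing 8 or more the correlation was 0.301. Neighbouring reading frames transcribed together may underlie the pattern, a hypothesis that stays open because the files do not say that the numbers follow the genome.

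The 2 lag arrays were less alike than lag and early exponential arrays, at r = 0.892 against 0.910 or more. A difference between first and second files shared by all phases could not be excluded: with it regressed out r was 0.902. Noise of dim probes stays open too, since the tests on bright probes part. Over the 259 brightest probes by mean over all arrays r was 0.829, below the lowest value of lag with early exponential arrays, 0.874, with a 95% interval of that difference of -0.07 to -0.005 from 10000 resamplings of probes. Over the 911 brightest it was 0.853 against a lowest value of 0.882, with an interval of -0.05 to -0.01. Over the 72 brightest it was 0.842 against a lowest value of 0.844, with an interval of -0.03 to 0.07, and over the 72 probes above the floor on all arrays 0.911 against 0.908. These intervals cover only the choice of probes, which are not independent, and leave out variation between arrays. The second minus the first lag array correlated at 0.392 with the change from early to late exponential phase and at 0.03 with that from early exponential to early stationary phase. The difference between first and second file in lag phase also correlated with that in late exponential phase, at 0.34, and at 0.18 with that in each of the other phases. Across all gene probes the second lag array correlated with the late exponential arrays at 0.902 and 0.911, and the first at 0.828 and 0.809. By correlation the second lag array thus lay nearer to late exponential phase, but with 1 sample this cannot be told apart from a difference between arrays.

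Of the 14 probes named after other database records, 1 exceeded the floor on 7 of the 8 arrays, with intensities of 1234 to 4449 over all 8, the lowest just under the floor of 1235 on the first early stationary array, and the others exceeded it on 0 arrays.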
